A study of Mus musculus with 11 samples.

How the data were processed

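Poly-A RNA from the nucleus accumbens of 1 mouse per library was made into TruSeq v2 libraries and sequenced as single-end reads on an Illumina instrument, per the labels' protocols. Groups and sizes were taken from the sample labels: GFP with saline (4), GFP with cocaine (3) and E2F3a with saline (4). The submitters' processing notes name Bowtie2 2.1.0, TopHat2 2.0.9, HTSeq 0.6.0 and the mm10 build, without saying what each was used for. The normalization, filter, annotation release and test program are not given in the sources used here.

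The authors deposited 2 tables of comparison statistics, cocaine against saline in GFP mice and E2F3a against GFP in saline mice, each with the same 14667 genes. Per the file headers, the columns hold a log2 fold change, a mean log2 expression, a t statistic and log odds (score columns), an unadjusted p-value and an adjusted p-value. The column names are those of a moderated test table of limma. The deposited mean log2 expression was identical in both tables, which share one fit, and 2 raised to it summed to 986624 over the genes, near the total that CPM values have. The deposited p-values matched a t distribution with 11.29 degrees of freedom in both tables, and the adjusted p-values matched a Benjamini-Hochberg adjustment over the 14667 genes. No columns of values per library were used, so the count-based tests planned beforehand were replaced by the fallback fixed with them, which is to use the authors' statistics without a refit. Depth per sample is unknown, and gene-level precision is known only as the standard error, with a median of 0.157 on the log2 scale for cocaine and 0.144 for E2F3a.

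The standard error of each gene was taken as log2 fold change divided by t, and 95% intervals used the same degrees of freedom. The ratio of the standard errors, cocaine over E2F3a, in the authors' deposited tables had a median of 1.08, as the group sizes give. It ran from 1.06 at the 5th percentile to 1.17 at the 95th. Equal weight for every library would give the same ratio for each gene, so that weighting is only an approximation here. Genes were called at an adjusted p under 0.05. Named genes followed a rule fixed before the data were examined. E2f3 came first. Genes past the adjusted threshold were to follow, and as none passed, the 12 genes with the smallest unadjusted p in each direction were taken among genes above the 25th percentile of mean expression (log2 of at least 3.21). From each fixed list up to 4 members with the smallest p could be named, and up to 6 genes shared by both comparisons in each direction; shared genes had no floor on expression. Coordinates are those of GENCODE M21, an annotation of the same assembly as mm10.

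Of 28 gene lists fixed before the data were examined, 27 had a measured member (419 of 466 entries); the mitochondrially encoded genes had 0 and are not analysed here. Lists were tested with cameraPR of limma 3.58.1 (R 4.3.3) on the deposited t, with a preset inter-gene correlation of 0.01, and Benjamini-Hochberg adjustment over the fixed lists of a comparison. Each median was also set among 10000 random lists matched on mean expression in 50 bins. Other computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9. The no-effect correlation and overlap were taken from 200 simulated sets of unchanged groups of 3 and 4 libraries against one group of 4, with the residual variance of each gene implied by the tables and genes drawn independently. Transcript length and GC content were those of the longest GENCODE M21 transcript, found for 14584 genes (99.4%), and trends were removed with cubic polynomials of log2 length and mean expression.

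The scripts were tested on simulated data with 200 genes changed by known folds among 14667, in 20 sets. In the cocaine comparison 34.7% of genes with a planted fold of 1.5, 69.9% at a fold of 2 and 92.0% at a fold of 4 passed an adjusted p of 0.05. In the E2F3a comparison the shares were 41.3%, 74.0% and 93.0%. On average 7.1 unchanged genes per set passed in the cocaine comparison and 6.25 in the E2F3a comparison. The simulated genes were independent with a nominal spread of t, while the deposited mean squared t was 1.46 of nominal for cocaine and 0.588 for E2F3a. The shares therefore do not give the power of the deposited tables. A planted shared covariance of 0.01 came back as 0.00992. That value was nearly fixed by construction, since each simulated pair was compared with itself without the planted effect, so it is no test of the method. Camera found 10 of 10 lists of 30 shifted genes and called 1 of 10 that were not shifted.

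Alternatives tried were an adjusted p of 0.1, an unadjusted p under 0.05 with a fold over 1.3, a floor on mean expression, a recomputed adjustment, Spearman's correlation, and lists ranked by log2 fold change. The preset correlations of 0.05, 0.1 and 0.3, the removal of trends, matching on length and the approximate test of the difference between effects were added after the tables were seen. A further 4 lists of cell type genes and 14 families or biotype groups were chosen after the tables were seen.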

Results

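RNA was sequenced from the nucleus accumbens, a region of the ventral striatum that takes part in reward, of 11 C57/BL6 mice. A virus carried either E2F3a, a variant of the transcription factor E2F3 that drives genes of the cell cycle, or green fluorescent protein (GFP) as a control. Mice received saline or cocaine, a stimulant that blocks dopamine reuptake. The groups were 4 mice with GFP and saline, 3 with GFP and cocaine, and 4 with E2F3a and saline, with 1 mouse per library. A group with E2F3a and cocaine was not analysed here. The values are the authors' comparison statistics for 14667 genes, so the level in each mouse and the depth of each library are unknown. Each SE and 95% interval below is the one implied by the deposited log2 fold change and its moderated t with 11.29 degrees of freedom.

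E2f3, the overexpressed gene, was higher in the E2F3a mice than in the GFP mice under saline. The authors' deposited table lists E2f3 (ENSMUSG00000016477, mm10 chromosome 13, 29906575 to 29986063, minus strand, a protein-coding gene) at a log2 fold change of 1.01 with an SE of 0.20 (95% interval 0.57 to 1.45), a fold of 2.02. Its unadjusted p was 0.000337 in the authors' deposited table, and its adjusted p over all 14667 genes was 1.00. Adjusted over the list alone, the list of 12 measured E2F family and pocket protein genes, the p was 0.00404. With cocaine against saline, the authors' deposited table gives E2f3 at -0.08 with an SE of 0.22. The tables do not separate transcripts of the virus from those of the chromosomal gene.

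The first comparison asked what cocaine changes in mice that carry only GFP. Transcripts of blood cells, leukocytes, dividing cells and microglia lay lower after cocaine, and glucocorticoid and clock genes and genes of the synapse lay higher as lists. At a preset inter-gene correlation of 0.3 the calls of the microglia (adjusted p = 0.173), clock (0.251) and synapse lists (0.382) were lost, the last also with the trend in transcript length removed (0.336). Hbb-bs, a beta-globin gene (ENSMUSG00000052305, mm10 chromosome 7, 103826534 to 103828096, minus strand), had the smallest p in the authors' deposited table, with a log2 fold change of -1.54 (SE 0.26, unadjusted p = 7.91e-05). By the authors' moderated test 0 genes passed an adjusted p of 0.05 in this comparison, where the smallest adjusted p in the authors' deposited table was 0.533. At an unadjusted p under 0.05 the authors' deposited table holds 1356 genes, 255 higher and 1101 lower, against 733.35 expected from uniform p values.

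The genes named next did not pass the adjusted threshold. Among the lower ones in the authors' deposited table were Fabp7, the fatty acid binding protein of radial glia and astrocytes, at -1.11 (SE 0.22), and Nupr1, a stress-induced nuclear protein, at -1.14 (SE 0.23). Igfbp2, which binds insulin-like growth factors, was listed at -1.48 (SE 0.34) in the authors' deposited table, and Ighm, the constant region of immunoglobulin M, at -0.96 (SE 0.21). The same authors' deposited table lists Cybrd1, a ferric reductase, at -0.90, Fam167a at -0.89, Hspb6, a small heat shock protein, at -0.79, Gramd3 at -0.62 and Ccdc80 at -0.61. On the higher side of the authors' deposited table, Per2, a repressor of the circadian clock (ENSMUSG00000055866, mm10 chromosome 1, 91415982 to 91459324, minus strand), stood at 0.63 (SE 0.16) and Per3 at 0.53 (SE 0.16). Acvr2a, a receptor for activins, had the smallest p of the higher genes in the authors' deposited table, with a log2 fold change of 0.41 (SE 0.09, unadjusted p = 0.000713). Arhgap26 and Arhgap6 were listed at 0.47 each in the authors' deposited table, Gda, a guanine deaminase, at 0.46 and Nhs at 0.46. The imprinted gene Mest stood at 0.44 in the authors' deposited table, Myrip at 0.38, Slc7a11, the cystine transporter, at 0.36 and Fam115a at 0.34.

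**Figure D1:**
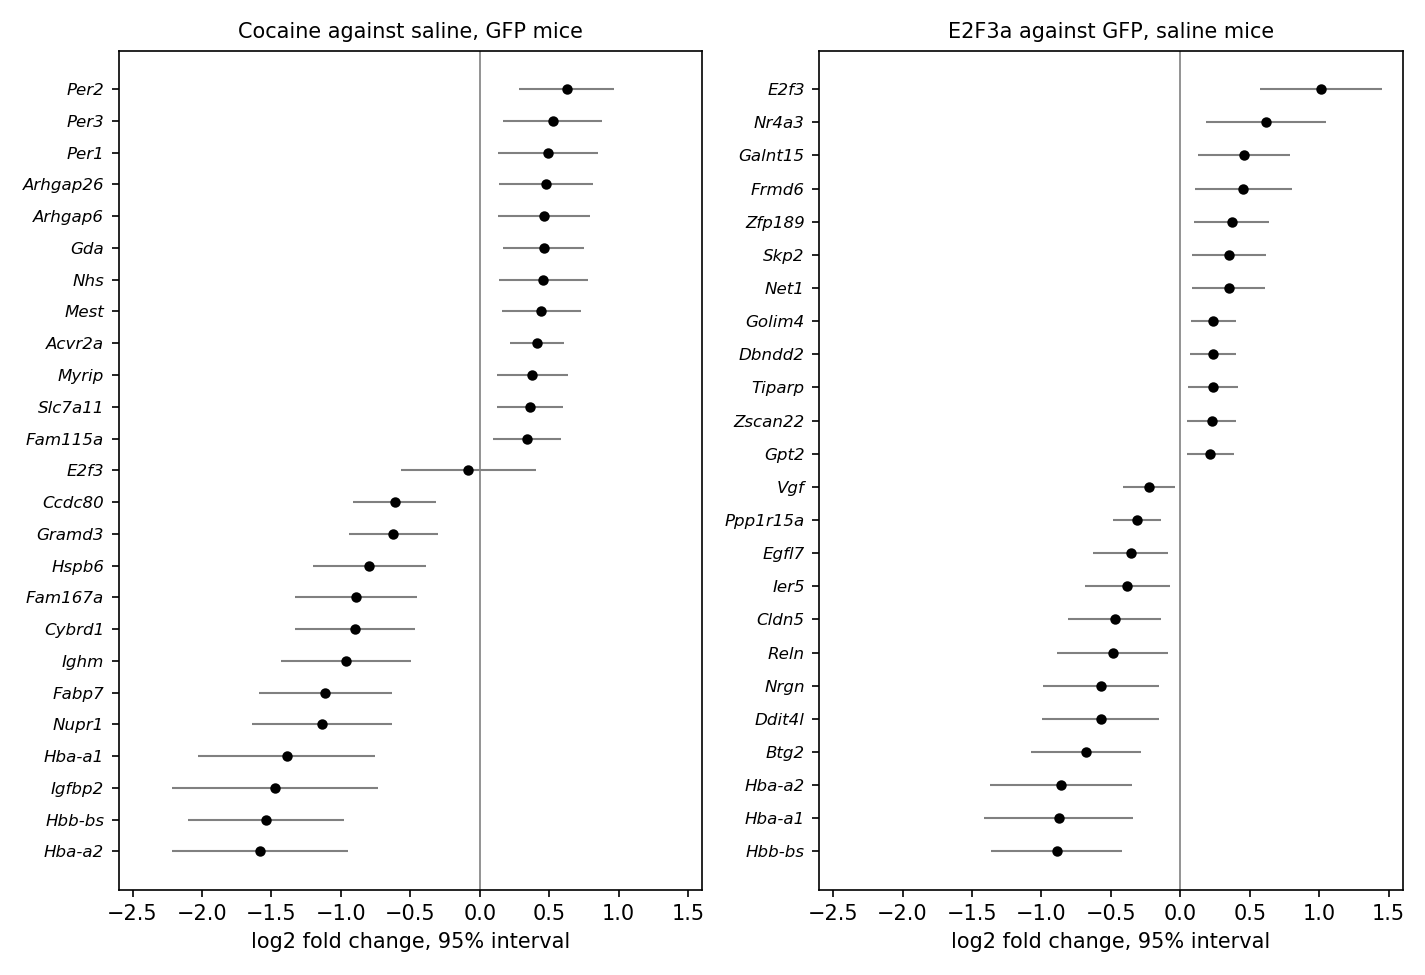
Log2 fold change (horizontal axis) of the genes with the smallest unadjusted p in each direction and of E2f3 in both comparisons, from the authors' deposited table of each. Points are the deposited estimates and lines their implied 95% intervals; E2f3 stands at 1.01 in the E2F3a comparison and at -0.08 in the cocaine comparison.

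Of 27 gene lists fixed before the data were examined, 11 were called in the cocaine comparison by limma's pre-ranked camera test with a preset inter-gene correlation of 0.01 (Benjamini-Hochberg adjusted p under 0.05), 9 lower and 2 higher. The correlation could not be estimated without values per mouse. With a preset correlation of 0.3 only 3 of these calls held, those of the blood, leukocyte and E2F target lists. A test not planned beforehand took the members of a list as fully correlated. By it the unadjusted p of the mean was 0.000337 for the blood list, 0.0217 for leukocytes, 0.0365 for E2F targets and 0.0681 for microglia. The same p was 0.191 for glucocorticoid and clock genes, 0.27 for endothelial and mural markers, 0.287 for the synapse list and 0.378 for interferon response genes. The blood cell list, made of globin genes and Alas2, had a median log2 fold change of -1.54 (adjusted p = 9.78e-15), and all 5 measured members passed when adjusted over the list alone. Hba-a2 was listed at -1.58 and Hba-a1 at -1.39 in the authors' deposited table, and since these copies are nearly identical, reads can be split between them either way. The leukocyte list had a median of -1.39 (adjusted p = 1.63e-08), with 10 of 12 members lower at an unadjusted p under 0.05 and the same number passing when adjusted over the list alone. Among its members, the authors' deposited table gives Cd79a, of the B cell receptor, at -2.34 (SE 0.61), Ly6c2, of inflammatory monocytes, at -1.72 (SE 0.49), and Cd3g and Cd3d, of the T cell receptor complex, at -1.76 (SE 0.58) and -1.57 (SE 0.54).

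The 34 measured E2F cell cycle target genes fell as a list after cocaine, with a median of -0.48 (adjusted p = 9.78e-15), and every one of the 34 estimates lay below 0. Of these, 21 were lower at an unadjusted p under 0.05, 13 were not, and 0 passed either over all genes or when adjusted over the list alone. Examples in the authors' deposited table are Rrm2 (-1.16, SE 0.33) and Rrm1 (-0.48, SE 0.15), the subunits of ribonucleotide reductase, and Ccnb1, cyclin B1 (-1.23, SE 0.38). The leukocyte and blood genes moved in the same direction in the same comparison. The 15 microglia markers had a median of -0.46 (adjusted p = 1.03e-05, and 0.173 at the preset correlation of 0.3), with 8 lower at an unadjusted p under 0.05. Tyrobp, an adaptor of microglial receptors, was at -0.74 (SE 0.27) in the authors' deposited table, and Aif1 at -0.54 (SE 0.21).

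The 5 remaining lower lists lost their call at a preset correlation of 0.05, with adjusted p from 0.064 to 0.112. These were the interferon response genes (median -0.22, adjusted p = 0.00588), p53 target and apoptosis genes (-0.25, 0.00801), endothelial and mural markers (-0.10, 0.0299), unfolded protein response genes (-0.19, 0.036) and reactive astrocyte genes (-0.33, 0.0413). The authors' deposited table has Bst2, an interferon-induced restriction factor, at -0.62 (SE 0.17), H2-K1, a class I histocompatibility gene, at -0.65 (SE 0.21), Cldn5, of the endothelial tight junction, at -0.59 (SE 0.17), Casp8 at -0.80 (SE 0.31), Ddit3 at -0.32 (SE 0.13) and Vim at -0.90 (SE 0.28). The glucocorticoid and clock genes were higher (median 0.26, adjusted p = 1.03e-05, and 0.251 at 0.3), with 7 of 21 members higher and 1 lower at an unadjusted p under 0.05. Per2 alone passed when adjusted over the list alone, and Per1 stood at 0.49 (SE 0.16) and Nfkbia, an inhibitor of NF-kappaB, at -0.51 (SE 0.18) in the authors' deposited table. The glutamate receptor and postsynaptic density genes were higher too (median 0.26, adjusted p = 0.000144, and 0.382 at 0.3), with 20 of 21 estimates above 0. In that list the authors' deposited table gives Shank2, a postsynaptic scaffold, at 0.47 (SE 0.19) and Grin2b, an NMDA receptor subunit, at 0.53 (SE 0.25). Longer transcripts lay higher in this comparison, and with the trend in length and expression removed the list was not called (adjusted p = 0.336). Its median still stood at percentile 99.93 of random lists matched on expression and length, and at 1.15 with E2F3a. Those lists were drawn gene by gene and so ignore correlation between genes. The immediate early genes, not called, stood at 99.54 with cocaine by the same measure. Ranking by log2 fold change ended the calls of the p53 target (adjusted p = 0.142), endothelial (0.276) and unfolded protein response lists (0.322), and removing the trend ended that of the last (0.21).

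The remaining lists were not called after cocaine, although the interneuron markers were with the length and expression trend removed (adjusted p = 0.0446). The medians were 0.11 for dopamine and cAMP signalling genes (adjusted p = 0.171), 0.10 for medium spiny neuron markers (0.245), 0.09 for D1 and 0.06 for D2 medium spiny neuron markers (0.464 and 0.764) and 0.17 for interneuron markers (0.246). Immediate early genes, which neuronal activity induces, had a median of 0.07 (adjusted p = 0.826), with 11 estimates above 0 and 9 below. The authors' deposited table gives Ier5 at -0.58 (SE 0.15), Ier2 at -0.67 (SE 0.20) and Nr4a3 at 0.42 (SE 0.22). Medians were 0.04 for deltaFosB targets (adjusted p = 0.682), 0.11 for chromatin regulators (0.0702), -0.01 for splicing regulators (0.552) and -0.17 for the E2F family (0.0911). Other cell type lists had medians of 0.07 for astrocytes (0.764), -0.07 for oligodendrocytes (0.898), 0.08 for their precursors (0.532), -0.03 for ependyma and choroid plexus (0.469), -0.39 for cortical neurons (0.767) and 0.23 for septal and neighbouring neurons (0.764). Among splicing regulators the authors' deposited table gives Rbfox2 at 0.34 (SE 0.12) and U2af1 at -0.28 (SE 0.11).

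**Figure D2:**
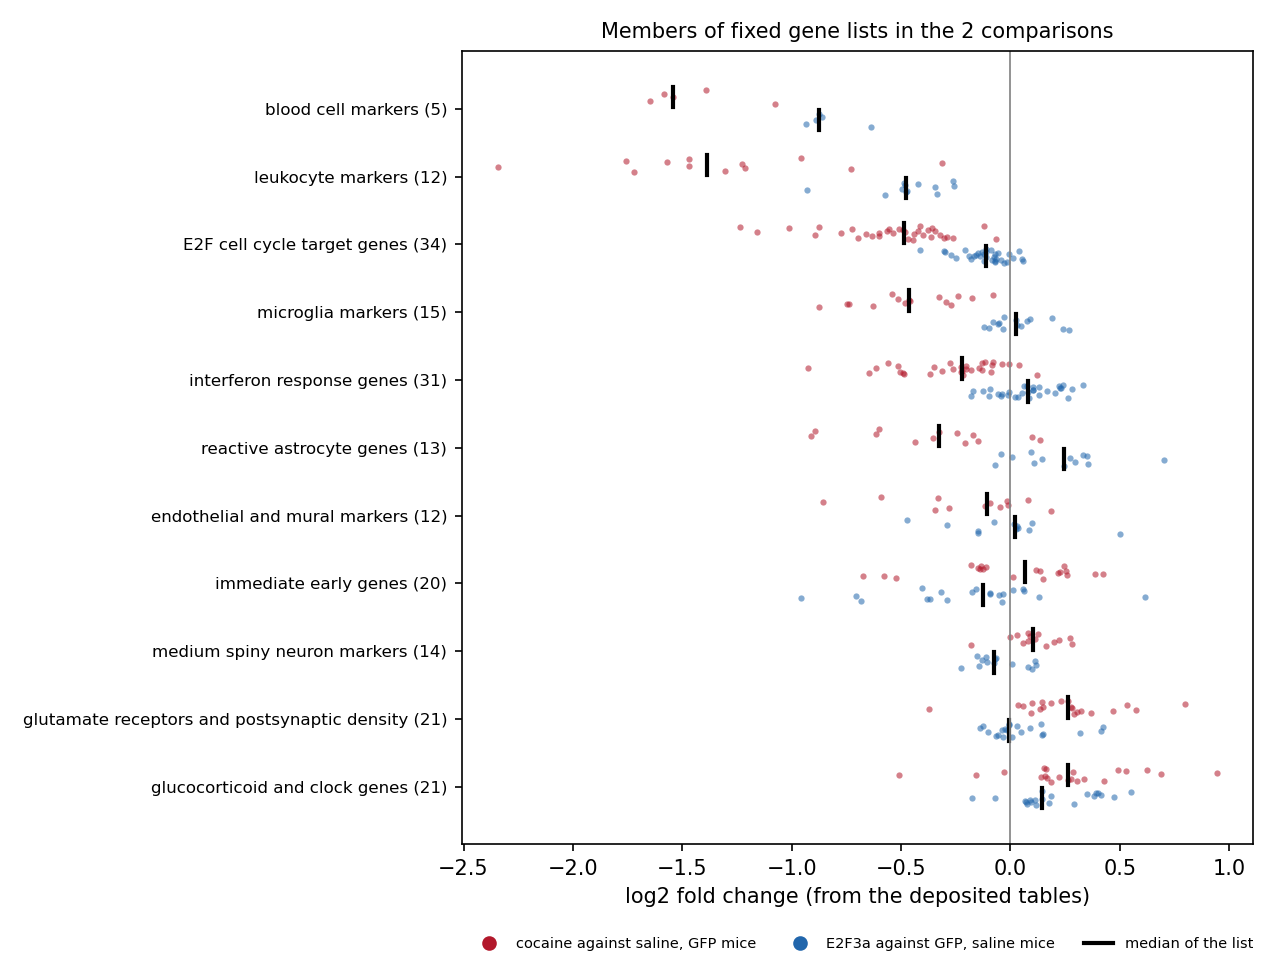
Log2 fold change (horizontal axis, from the authors' deposited table of each comparison) of the members of 11 of the fixed gene lists, 1 point per gene, red for cocaine against saline and blue for E2F3a against GFP, with the number of measured members in brackets and a black bar at each median. The blood cell list lies at medians of -1.54 and -0.87, and the E2F cell cycle targets at -0.48 and -0.11.

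The second comparison asked what E2F3a overexpression changes in mice given saline. E2f3 itself was higher, globin genes lay lower, and neither the E2F target genes nor the splicing regulators were higher as lists. No gene in the authors' deposited table passed an adjusted p of 0.05 by their moderated test (0 of 14667), and 140 had an unadjusted p under 0.05, 80 higher and 60 lower, against 733.35 expected from uniform p values. The mean squared t was 0.588 of its nominal value here and 1.46 of it for cocaine, so p values and counts may not be comparable between the tables. After E2f3, the higher genes with the smallest p above the expression floor in the authors' deposited table were Golim4 (0.24, SE 0.07), Dbndd2 (0.24, SE 0.08) and Nr4a3, an inducible nuclear receptor (0.62, SE 0.20). Skp2, a ubiquitin ligase subunit that acts in the cell cycle, was at 0.35 (SE 0.12) in the authors' deposited table, as was Net1 (0.35, SE 0.12). Galnt15 (0.46), Frmd6 (0.45), Zfp189 (0.37), Tiparp (0.23), Zscan22 (0.23) and Gpt2 (0.22) complete the higher genes from the authors' deposited table.

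On the lower side of the E2F3a comparison, the authors' deposited table lists Hbb-bs at -0.89 (SE 0.21), Hba-a1 at -0.87 (SE 0.24) and Hba-a2 at -0.86 (SE 0.23). Btg2, an antiproliferative immediate early gene, was at -0.68 (SE 0.18) in the authors' deposited table, and Ppp1r15a, which promotes recovery from translational arrest, at -0.31 (SE 0.08). Nrgn, a calmodulin-binding protein of dendrites, was at -0.57 (SE 0.19) and Cldn5 at -0.47 (SE 0.15) in the authors' deposited table. The authors' deposited table further lists Ddit4l (-0.57), Reln, an extracellular matrix glycoprotein (-0.49), Ier5 (-0.38), Egfl7 (-0.36) and Vgf, a neuropeptide precursor (-0.22).

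In this comparison 8 of the 27 lists were called, 5 lower and 3 higher, and with a preset correlation of 0.3 only the blood cell list held. It had a median of -0.87 (camera adjusted p = 1.44e-19), and all 5 members passed when adjusted over the list alone. The blood list was low with cocaine too, and both comparisons use the same GFP and saline mice, so these results are not separate evidence. Without values per mouse, a higher level of blood transcripts in those control mice cannot be told apart from an effect of E2F3a on this list. The leukocyte list had a median of -0.48 (adjusted p = 4.26e-05, and 0.187 at 0.3), with all 12 estimates below 0 and 0 of 12 at an unadjusted p under 0.05. The 34 E2F cell cycle targets had a median of -0.11 (adjusted p = 0.000893, and 0.165 at a preset correlation of 0.1). None of those 34 genes had an unadjusted p under 0.05, and 30 estimates lay below 0. Immediate early genes were lower as a list (median -0.13, adjusted p = 3.06e-05, and 0.271 at 0.3), with 2 of 20 lower and 1 higher at an unadjusted p under 0.05. The unfolded protein response list was lower (median -0.09, adjusted p = 0.0404, and 0.137 at a preset correlation of 0.05), a call also lost when ranked by log2 fold change (0.355) or with the trend removed (0.29). With members taken as fully correlated, the unadjusted p of the mean was 0.00452 for the blood list and 0.296 for leukocytes. By that test it was 0.573 for E2F targets and 0.281 for glucocorticoid and clock genes. It ran from 0.79 to 0.875 for the endothelial, interferon, microglia and synapse lists, which were not called here.

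The glucocorticoid and clock genes were higher with E2F3a as well (median 0.15, adjusted p = 1.47e-06, and 0.187 at 0.3), with 5 of 21 at an unadjusted p under 0.05 and 0 passing when adjusted over the list alone. Sgk1, a kinase induced by glucocorticoids, stood at 0.55 (SE 0.20) in the authors' deposited table, Per1 at 0.40 (SE 0.15) and Per2 at 0.39 (SE 0.15). Ependymal and choroid plexus markers had a median of 0.41 over 6 measured genes (adjusted p = 0.000893, and 0.187 at 0.3), of which 0 had an unadjusted p under 0.05. The astrocyte markers had a median of 0.16 (adjusted p = 0.0404, 0.129 at a preset correlation of 0.05, and 0.056 when ranked by log2 fold change), with Slc1a3, a glutamate transporter, at 0.29 (SE 0.13) in the authors' deposited table.

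The other lists were not called with E2F3a by the test on the deposited t. Reactive astrocyte genes were called as higher when ranked by log2 fold change (adjusted p = 0.008) or with the length and expression trend removed (0.00862), and oligodendrocyte markers with that trend removed (0.0291). Splicing regulators had a median of 0.03 over 47 genes (adjusted p = 0.487), with 0 at an unadjusted p under 0.05. Chromatin regulators had a median of 0.04 (adjusted p = 0.271), deltaFosB targets 0.0021 (0.754), p53 targets -0.01 (0.487), the interferon response 0.08 (0.487) and the E2F family 0.04 (0.271). Neuronal lists had medians of -0.02 for dopamine and cAMP signalling (0.671), 0.07 for D1 and -0.08 for D2 medium spiny neurons (0.681 and 0.294), -0.07 for medium spiny neurons (0.487), 0.04 for interneurons (0.379) and -0.0045 for glutamate receptors and the postsynaptic density (0.671). Medians were 0.24 for reactive astrocytes (0.0575), 0.03 for microglia (0.65), 0.13 for oligodendrocytes (0.144) and for their precursors (0.294), 0.02 for endothelium (0.294), 0.49 for cortical neurons (0.609) and -0.03 for septal neurons (0.661). Within the cortical list Nrgn, which had the smallest SE of the 4 members, was lower and passed when adjusted over the list alone (p = 0.0475 from the unadjusted p of the authors' deposited table). Median, mean and camera direction differed in sign for 11 results, none of them called. These were the immediate early, splicing, oligodendrocyte and ependymal lists with cocaine, and the interneuron, glutamate receptor, deltaFosB, p53, endothelial, cortical and septal lists with E2F3a.

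The third question was how far the E2F3a effect resembles the cocaine effect, since both were measured against the same 4 GFP and saline mice. At an unadjusted p under 0.05 with a fold over 1.3, the authors' deposited tables hold 1030 genes for cocaine and 86 for E2F3a. Of these, 17 were higher in both, 20 were lower in both and 0 went in opposite directions. Unchanged groups simulated against one set of 4 controls shared 25.1 higher and 24.8 lower genes, and independent lists of the observed sizes would share 0.489 and 2.38. The simulated counts are not on the observed footing, since the simulated sets held on average 303 genes for cocaine and 268 for E2F3a at this level. Of the observed E2F3a genes, 17 of the 46 higher and 20 of the 40 lower ones were shared. The higher ones include Pde11a, a phosphodiesterase, listed in the authors' deposited tables at 1.40 (SE 0.48) with cocaine and 1.37 (SE 0.45) with E2F3a, and Per2 and Per1. The lower ones include the globin genes Hbb-bs, Hbb-bt, Hba-a1 and Hba-a2, with Cldn5 and Ddit4l, whose values in the authors' deposited tables were -0.69 (SE 0.22) with cocaine and -0.57 (SE 0.19) with E2F3a for the last.

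Across the 14667 genes, which are not independent replicates, the log2 fold changes of the authors' deposited tables correlated with Pearson's r of 0.626 and Spearman's rho of 0.604. Unchanged groups against shared controls gave a mean r of 0.461. The covariance was 0.0495 against a simulated 0.0274. Part of the excess may come from the shared controls, which could not be split without values per mouse.

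An approximate test of the difference, E2F3a minus cocaine effect, was added after the tables were seen and rests on equal weight for each library. It called 0 genes at an adjusted p of 0.05. At an unadjusted p under 0.05 it held 663 genes, fewer than the 733.35 expected from uniform p values, and 600 of them had the higher estimate in E2F3a. As lists, camera called 8 higher and 5 lower with E2F3a than with cocaine. The higher ones were the E2F cell cycle targets (median difference 0.40, adjusted p = 1.24e-12), microglia markers (0.43, 3.87e-09), interferon response genes (0.33, 2.99e-05), leukocyte markers (0.97, 1.77e-05), reactive astrocyte genes (0.60, 1.89e-05), blood cell markers (0.65, 0.000189), the E2F family (0.21, 0.00076) and p53 targets (0.35, 0.00566). The E2F family list includes E2f3, the overexpressed gene, which had the highest difference of the list (1.10, SE 0.22). That list was not tested without E2f3. The lower ones were glutamate receptor and postsynaptic density genes (median difference -0.24, adjusted p = 1.2e-05), immediate early genes (-0.18, 0.00535), interneuron markers (-0.23, 0.016), medium spiny neuron markers (-0.16, 0.0229) and dopamine and cAMP signalling genes (-0.15, 0.024). Of these 13 calls, 0 held at a preset correlation of 0.3.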

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

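The approximate difference test, the preset correlations above 0.01, matching on length, the removal of trends or of list members and the E2f3 adjustment over its list were chosen after the tables were seen. Counts of called genes stayed at 0 for both comparisons and their difference at an adjusted p of 0.1, with the adjustment recomputed and above the 25th percentile of mean expression. The difference also stayed at 0 with the control variance taken from either table alone. At an unadjusted p under 0.05 with a fold over 1.3 they became 1030 for cocaine, 86 for E2F3a and 505 for the difference, and the overlap went from 0 to 37, because that level carries no correction for the number of genes. The correlation of 0.626 was 0.604 with Spearman's rho and 0.587 above the median of mean expression. These moves were set against 0.0204, the simulated SD of Pearson's r, which replaced 0.05 after the values were seen. That SD assumes independent genes and does not measure a spread between measures. Without effect the simulated mean was itself 0.461 for Pearson's r and 0.425 for Spearman's rho. The cause of the moves was not tested. Pearson's r was 0.623 without the immune, blood, endothelial and E2F target members. Called lists went from 11 to 6, 6 and 3 for cocaine at preset correlations of 0.05, 0.1 and 0.3, and from 8 to 6, 5 and 1 for E2F3a, since a higher preset correlation widens the test. Random lists matched on expression placed 14 lists of each comparison in the outer 2.5% on either side, and those matched on length as well placed 17 for cocaine and 16 for E2F3a; the cause was not tested. The adjusted p of E2f3, 1.00 over all genes, was 0.00404 over its list of 12, which tests fewer genes. No list changed direction among those called.

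No paired analysis was possible because the tables carry no values per mouse. For the same reason other normalizations, filters, pseudocounts and count tests, leaving out each library, fits on the groups of 1 comparison only, other splits of the samples, split controls, fry and an estimated inter-gene correlation were not run. How much 1 mouse decides any value, or what depth limits, is therefore unknown.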

Other observations

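The added lists and families, and the tests of leukocyte RNA in the shared controls, on the leukocyte and on the second list, and of the slope of the difference, were chosen after the tables were seen. Adjusted p values were corrected separately over the 4 added lists, over the families and over the biotype groups, not over all of these together. Other lists of immune cell genes were lower in the cocaine table. The 10 B and plasma cell genes had a median log2 fold change of -2.58 (camera adjusted p = 1.51e-08) with cocaine and -1.14 (1.13e-08) with E2F3a. The 25 monocyte and macrophage genes, of which Ly6c2 is also on the leukocyte list, stood at -0.73 (2.82e-07) and -0.19 (0.00476). T cell receptor segments had a median of -1.22 over 26 genes (1.67e-06) with cocaine and -0.21 (0.0533) with E2F3a, and immunoglobulin segments -2.19 over 24 genes (4.54e-05) and -1.14 (2.49e-09). Both groups lie near the floor, with mean log2 expression of -2.19 and -2.78 in that order, against a median of 4.79 over all genes. Immunoglobulin estimates with cocaine ran from -5.07 to 1.69. This group and the B and plasma cell list may share genes, so their calls are not separate evidence. The immunoglobulin group was limited to Ig symbols after its content was seen, and reads of such near-identical segments and of histocompatibility genes can be split between copies. Class I and II histocompatibility genes stood at -0.49 (2.81e-07) and -0.14 (0.00374). Meningeal and perivascular fibroblast genes stood at -0.17 (0.652) and 0.13 (0.015, and 0.0573 at a preset correlation of 0.05). At a preset correlation of 0.3 the B and plasma cell calls held (adjusted p = 0.0034 with cocaine and 0.00621 with E2F3a). That list was weakly expressed too, with a mean log2 expression of 0.66. Of its 10 members, 6 were lower at an unadjusted p under 0.05 with cocaine and 2 with E2F3a. The immunoglobulin segments held there with E2F3a (0.0459), adjusted over the biotype groups alone. With cocaine the calls of monocyte genes (0.0579), T cell receptor segments (0.149), immunoglobulin segments (0.149) and histocompatibility genes (0.132) were lost at 0.3. With E2F3a that of histocompatibility genes was lost at 0.05 (0.05003) and that of monocyte genes at 0.1 (0.104).

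With cocaine, protocadherin genes had a median of 0.23 (camera adjusted p = 3.38e-08), GABA receptor genes 0.31 (0.000123), calcium channel genes 0.26 (5.7e-05) and voltage-gated potassium channel genes 0.23 (9.8e-05). All 79 cytosolic ribosomal protein genes had estimates below 0 with cocaine, with a median of -0.30 (1.08e-13), and respiratory chain genes stood at -0.17 (9.8e-05). With E2F3a, the medians were 0.11 (0.00179), 0.14 (0.0492), 0.06 (0.264), 0.08 (0.211), -0.09 (2.53e-06) and -0.09 (5.57e-09) in the same order. Other families had medians with cocaine and with E2F3a of -0.22 (0.386) and 0.09 (0.019) for collagens, -0.24 (0.122) and 0.06 (0.708) for chemokines, -0.13 (0.537) and -0.18 (0.019) for histones, 0.06 (0.000514) and 0.05 (0.00812) for zinc finger proteins, and 0.05 (0.0194) and 0.03 (0.433) for long intergenic noncoding RNAs. With cocaine the calls of the protocadherin, GABA receptor, calcium channel and ribosomal protein genes (adjusted p = 0.132 each) and of the potassium channel genes (0.212) were lost at a preset correlation of 0.3, and that of the respiratory chain genes at 0.1 (0.121). With E2F3a the calls of the ribosomal protein (0.127) and respiratory chain genes (0.0715) were lost at 0.1, and those of protocadherin (0.05003), GABA receptor (0.129), collagen (0.0985), histone (0.0742) and zinc finger genes (0.204) at 0.05. The cocaine calls of zinc finger genes (0.105) and long intergenic noncoding RNAs (0.233) were lost at 0.05 as well. Among random lists matched on expression and length, the respiratory chain median stood at percentile 6.43 with cocaine and 3.25 with E2F3a. By the same measure with E2F3a, the protocadherin median stood at percentile 96.265 and the collagen median at 71.36.

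Leukocyte, blood and cell cycle genes were lower together in the cocaine table. The tables argue against a trend with transcript length, since the 51 pooled members kept a median of -0.577 after length and expression trends were removed, against -0.633 before. A smaller share of leukocytes in the cocaine samples stays open, since a second list of 34 measured T and NK cell genes, none of them on a fixed list, had a median of -1.24 (-0.32 with E2F3a) but was chosen when the leukocyte list had been seen low and so restates it, and its most abundant members, Coro1a and Selplg (deposited mean log2 expression 6.98 and 6.53), which microglia also express, stood at only -0.57 and -0.47 with cocaine in the authors' deposited table. More leukocyte RNA in the saline control mice would lower both tables alike. Camera on the difference at a preset correlation of 0.3 did not call the fixed leukocyte list (median difference 0.97, adjusted p = 0.114). The second list (0.857, 0.0187) and the B and plasma cell genes (1.32, 0.0432) were called there. Both were chosen after the tables were seen, so they are not separate evidence against this explanation. Their p values were adjusted over the 4 added lists only, not over all lists and families added. This explanation stays open, because with members taken as fully correlated the mean differences had p = 0.0939 for the leukocyte list (0.878, SE 0.480), 0.0799 for the second list and 0.139 for the B and plasma cell genes. Whether the cell cycle genes belong to those leukocytes was not tested, and an effect of cocaine on them stays open.

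The correlation of both tables across genes was above the simulated value. The tables argue against the length trend as the whole cause, since with it removed Pearson's r was 0.607 (simulated without effect, 0.461) and Spearman's rho 0.519 (0.425), but rho had been 0.604, so the trend may carry part of the rank correlation. Shared controls cannot be told apart from a shared effect, although the covariance was 1.81 times the simulated one and so passed the bound of 1.70 written beforehand, the largest departure of a table's mean squared t from nominal (0.588 of it for E2F3a, and 1.46 of it for cocaine). That bound was set aside after the value was seen, because real effects raise a mean squared t on average, so that 0.588 for E2F3a shows that chance or the authors' weights alone may move such a ratio by the whole of the bound, which is then the size of 1 departure and no limit on it, and the simulation of independent genes gives no spread for genes that move together. No biological explanation was tested.

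Longer transcripts lay higher in both tables, with a rank correlation of 0.503 for cocaine and 0.496 for E2F3a above the 25th percentile of expression, and 0.335 and 0.341 over all 14584 genes with a length. The tables argue against GC content, as the partial correlations with GC and expression held constant were 0.482 and 0.463 above that percentile and 0.302 and 0.337 over all genes. A changed share of short immune and glial transcripts could be a cause and stays open, as within the neuronal lists (68 genes) the correlation was 0.392 for cocaine (permutation p = 0.001) but 0.182 for E2F3a (permutation p = 0.143). The shared controls may carry part of it and stay open. Above that percentile the slope per doubling of length was 0.13 for cocaine, 0.07 for E2F3a and -0.0604 for their difference. That difference is neither within 0.02 of 0, as the shared controls would give, nor further from 0 than the E2F3a slope, the limit set against them. Over all genes the slopes were 0.0267, 0.0183 and -0.0084. The E2F3a slope there is itself within 0.02 of 0, so the small difference cannot decide. RNA quality per mouse is unknown, and no biological explanation was tested.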
